A study of Daphnia magna with 8 samples.

How the data were processed

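Total RNA of whole *Daphnia magna* neonates was labelled with Cy3 and hybridised to one-colour arrays of 1 custom design, per the labels. The deposited scanner files hold spot intensity values written by Agilent Feature Extraction 9.5.3.1 from images of a GenePix 4000B scanner, per the file headers. Per the file headers, the processed intensity of a spot had its background subtracted and was detrended within the array, surrogate values replaced spots not above background, and nothing was done between arrays. The raw mean and local background intensity and the flags for spots well above background, saturated or uneven were used as deposited. The deposited value table of the same arrays is on the log2 scale, and its steps are not given in the sources used here. Set against the scanner values, each column equalled log2 of the processed intensity minus the array's 75th percentile and minus the probe's mean over the 4 DMF arrays (r of 1 on each array, median absolute difference at most 0.000423). Its scale, centring and direction were thereby settled. The column medians ran from -0.05 to 0.06.

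Samples were grouped by the treatment in their labels, 4 DMF and 4 diofenolan, and named by group and replicate. The file headers put all DMF arrays on slide 1 and scan 1 and all diofenolan arrays on slide 2 and scan 2, so batch and group cannot be told apart and no blocked fit for the slide could be made. The 75th percentile of the processed signal ran from 298 to 373 on the DMF arrays and from 300.3 to 389 on the diofenolan arrays. Between 233 and 323 probes were saturated on an array. Array values correlated at 0.984 to 0.994 within groups and 0.970 to 0.983 between groups, and no pair of arrays held identical values.

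Log2 of the processed signal minus the array's 75th percentile over non-control probes was the measure. Control spots were left out, and non-uniform and population outlier spots were treated as missing. A probe was tested where it was well above background on at least 3 of the 4 arrays of either group and had at least 2 usable arrays in each group, which left 25816 of 43803 probes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, treatment the only term, 2-sided) with Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Fold changes are diofenolan minus DMF. Where a probe was well above background on no array of a group, only a bound is given. It sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

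The array files give each probe's ID and sequence and no gene name or description. None (0) of the probe IDs or their stems matched the 28335 genes of the reference table supplied, so the gene lists and the rules for named genes fixed before the data were examined could not be applied, and genes as the unit were not run. In that case the rule allowed the 2 probes with the largest rise and the 2 with the largest fall among changed probes whose groups did not overlap, and these are given by ID with their sequences. The probes were 50 or 60 bases long, with 38705 different sequences among them.

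Motif groups were built from the probe sequences in their place. Each sequence was translated in its forward frames (Biopython 1.88), and frames with no stop were searched with written patterns for 16 protein families. The patterns were written after the sequences, their hits and their mean signals had been seen and before any fold change was computed. A group was used where its patterns hit at least 3 times as many probes as in the reversed sequences and at least 5 tested probes carried it, which left 4 groups. A motif describes the peptide a probe would encode and names no gene. Groups were tested with camera at its preset correlation of 0.01, adjusted over the 4 groups, and again with an estimated correlation and with fry.

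The fit was tested on simulated data drawn for 25819 probes with the measured means and spreads and 200 changed probes. It recovered 73 of 100 probes changed by a log2 of 1 and 12 of 100 changed by 0.5, with 5 unchanged probes called. With only 200 changed probes the adjusted threshold was stricter there than in the measured data, so these shares do not carry over to it. Comparisons of single values used exact permutation tests (scipy 1.17.1). Alternatives were other scalings and background corrections, other filters, the replicate number as a block, other moderation, array weights, other thresholds, the deposited value table and each array left out in turn. The value table is the same measure minus a constant per probe, so it is no separate test in any count of settings. Alternatives and tests added after the data were seen are named as such. All alternatives run on the motif groups were outside the plan, as the groups themselves were. The p-values measure the spread between the pools hybridised within each slide.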

Results

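Whole-body RNA of newborn water fleas (*Daphnia magna*) was measured on 8 one-colour arrays after 48 h of exposure. Diofenolan, an insect growth regulator that acts as a juvenile hormone analogue, was given at 10 ng/L to 4 samples, and 4 samples received the control labelled DMF. Each sample was a pool of at least 20 animals, so a value is an average over animals. The series design speaks of 4 independent experiments and the extraction protocol of 3, and the labels do not settle which is right for these arrays. Each array carried 43803 probes, of which 57.3% to 59.3% were well above background on the DMF arrays and 56.1% to 60.6% on the diofenolan arrays. The number of arrays limits the precision of every value below.

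The comparison addressed which transcripts differed between animals exposed to diofenolan and control animals, in a study of juvenile hormone-like action in this crustacean. Transcripts differed widely, mostly by modest amounts, and by the fitted values large rises were more frequent than large falls. Of 25816 probes tested, 3001 were higher and 2794 lower after diofenolan, with median folds of 1.59 and 1.40. With each array centred on its median in place of its 75th percentile, the split was 2320 higher and 5120 lower (31.2% higher against 51.8%), since the median log2 fold change of all tested probes then stood at -0.13 in place of -0.03. Probes that rose at least 2-fold numbered 739, against 82 that fell by as much, and 77 rose and 0 fell at least 4-fold. The rises and the falls counted here include probes well above background on no array of a group. For those the fitted fold is no measured size and only a bound holds, and no recount without them was made. Of the 739 probes, 179 (24.2%) had IDs that start with CU. Among the motif groups of probes, the cuticle protein group shifted upward as a set (camera adjusted p = 0.00106; adjusted p = 0.159 with an estimated correlation). All 4 DMF arrays lay on slide 1 and all 4 diofenolan arrays on slide 2, so slide and treatment cannot be told apart in any of these differences.

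The RR motif is the chitin-binding consensus of many arthropod cuticle proteins, and 6 tested probes encode it. Of these, 3 rose, 0 fell and 3 did not pass the test over all probes, while all 6 had values above 0. The median log2 fold change of the group was 0.51, a fold of 1.42. The probe of lowest p in the group rose by 1.87 ± 0.16 (SE) on the log2 scale, a fold of 3.66 (4 arrays per group, limma adjusted p = 0.000248). The other risen cuticle probes had log2 fold changes of 1.00 ± 0.16 (SE) and 0.77 ± 0.14 (SE), with limma adjusted p of 0.00432 and 0.00628. Adjusted over the group alone, 5 of the 6 passed, where the same adjustment passed 1 trypsin-type, 3 thioredoxin fold and 2 ubiquitin probes of the groups described next. The set test gave an upward shift of this group against all other probes (camera adjusted p = 0.00106 over 4 groups), and the call was lost with a correlation estimated from the data (adjusted p = 0.159 with an estimated correlation).

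Probes that encode the active-site motifs of trypsin-type serine proteases, which include the main digestive proteases of *Daphnia*, numbered 19 among those tested, with 16 different sequences. In this group 3 rose, 0 fell and 16 did not pass, and the median log2 fold change was 0.02 (camera adjusted p = 0.129; adjusted p = 0.435 with an estimated correlation). The risen protease probes had log2 fold changes of 0.79 ± 0.10, 0.62 ± 0.17 and 0.35 ± 0.11 (SE). Other tested probes with the sequence of the second had 0.61 ± 0.30 and 0.45 ± 0.22 (SE). These did not pass (limma adjusted p = 0.169 and 0.173). With each array centred on its median in place of its 75th percentile, an alternative not planned for the motif groups, the median of the protease group was -0.08.

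Thioredoxin fold probes, whose motif is the redox-active site of thioredoxins and protein disulfide isomerases, split in direction. Of 7 tested, with 5 different sequences, 1 rose by 0.94 ± 0.09 (SE) and 1 fell by 0.33 ± 0.10 (SE) on the log2 scale. The other 5 probes did not pass. As a set the group had a camera adjusted p of 0.22, and an adjusted p of 0.435 with an estimated correlation. The median of this group was 0.05, and -0.05 with arrays centred on their medians, which was not planned for it. Probes of 1 shared sequence stood at 0.05, -0.002 and -0.0007, and the first of them gave the group median. Of 7 tested probes that encode the ubiquitin signature, the tag that marks proteins for degradation, 2 rose, 0 fell and 5 did not pass. Their median log2 fold change was 0.37 (camera adjusted p = 0.127, and adjusted p = 0.435 with an estimated correlation). In fits not planned for this group, it ran from 0.11 without diofenolan replicate 4 to 0.53 without diofenolan replicate 2. The risen ubiquitin probes had values of 1.41 ± 0.28 and 0.47 ± 0.14 (SE). Tested for a shift in one direction on their own, without setting them against other probes, the groups had fry adjusted p of 0.00061 (cuticle), 0.0321 (thioredoxin fold), 0.0628 (trypsin-type) and 0.144 (ubiquitin).

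**Figure D1:**
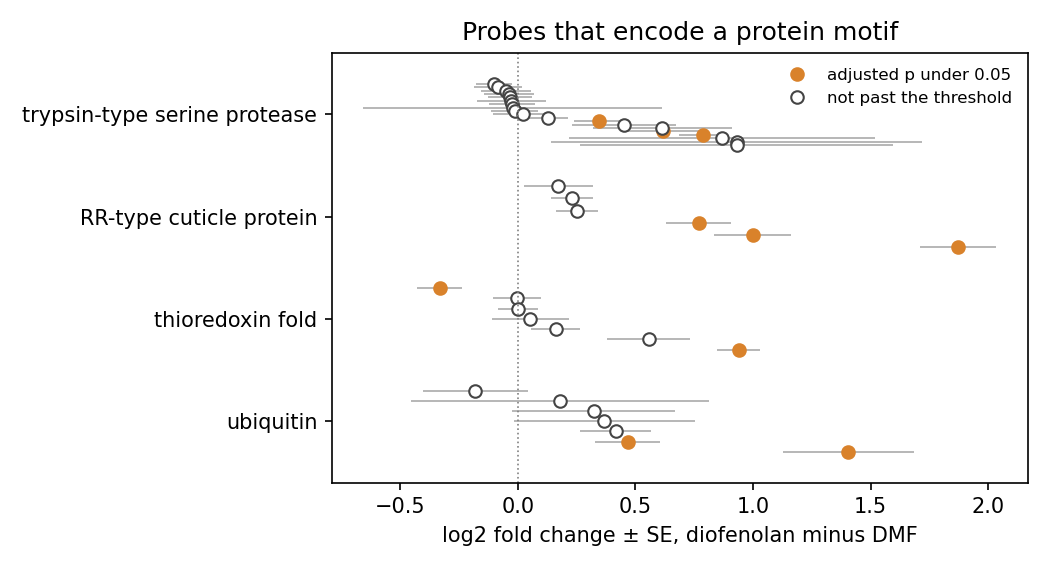
Log2 fold changes (diofenolan minus DMF, 4 arrays per group) of each tested probe in 4 motif groups, with bars of 1 SE; filled points passed an adjusted p of 0.05. All 6 cuticle protein probes lie above 0, from 0.17 to 1.87.

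At the level of single probes, the largest rise by the fitted value was that of probe DMAG0001S00005486 (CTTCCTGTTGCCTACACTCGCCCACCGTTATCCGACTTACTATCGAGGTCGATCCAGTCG). It was well above background on 0 of 4 DMF arrays and 4 of 4 diofenolan arrays, so only a bound holds, at least 6.47-fold higher after diofenolan. The limma adjusted p = 0.000325 belongs to the fitted value and does not test the bound. With normexp fitted from the negative controls, an alternative added after the data were seen, the bound was lower, at least 3.36-fold. Another probe of the same sequence was also higher (limma adjusted p = 0.00138) and well above background on 0 DMF arrays. Probe DM12433_2 (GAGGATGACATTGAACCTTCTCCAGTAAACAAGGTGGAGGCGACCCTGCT) rose from a mean log2 level of -2.43 ± 1.62 to 0.98 ± 0.96 (SD, n = 4 each), a log2 fold change of 3.41 ± 0.77 (SE; limma adjusted p = 0.0153). It was well above background on 3 of the DMF arrays, and without DMF replicate 4, which stood at -4.71, its log2 fold change was 2.65.

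Probe DM05284_2 (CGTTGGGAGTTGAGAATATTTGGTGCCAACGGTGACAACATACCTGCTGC) fell by 1.78 ± 0.26 (SE) on the log2 scale, from -1.43 ± 0.48 to -3.22 ± 0.40 (SD, n = 4 each; limma adjusted p = 0.00276), and was well above background on 2 of the diofenolan arrays. Its mate of the same ID stem had a log2 fold change of -0.87 ± 0.13 (SE). Probe DM09502_2 (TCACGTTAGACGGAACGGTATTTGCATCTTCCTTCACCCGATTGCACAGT) was well above background on 3 DMF arrays and 0 diofenolan arrays, and was at least 1.13-fold higher in the DMF group. Its limma adjusted p = 0.00207 likewise belongs to the fitted value and does not test this bound. With normexp fitted from the negative controls, the log2 fold changes of DM12433_2 and DM05284_2 were 2.45 and -0.92, and the bound of DM09502_2 was at least 1.06-fold. Under the planned normexp with the 75th percentile, DM12433_2 and DM05284_2 had 1.99 and -0.93, and all 4 named probes lost their call. That fit left a raised floor on DMF array 3. The files pair none of these probes with a gene, and each probe was on 1 slide per group like all others.

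**Figure D2:**
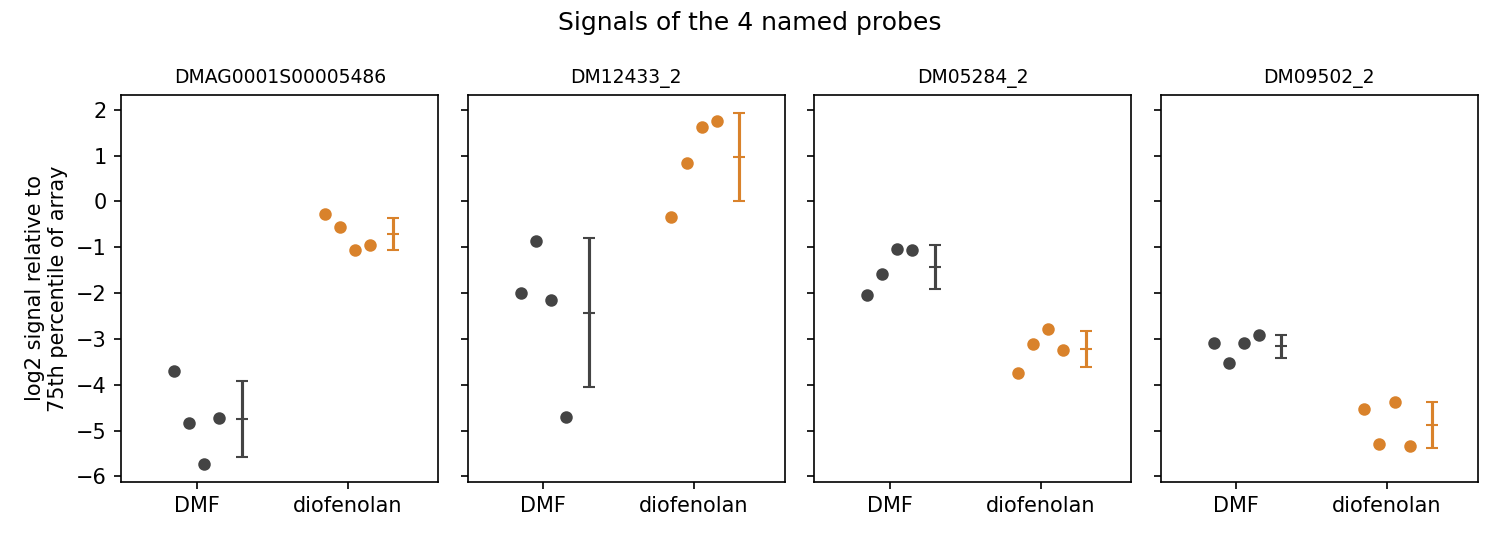
Log2 signal relative to the 75th percentile of the array for 4 probes, each point 1 array and the bar the mean ± SD of 4 arrays in the DMF and diofenolan groups. In each panel the 4 arrays of a group lie on one side of the 4 arrays of the other, and for DMAG0001S00005486 (DMF) and DM09502_2 (diofenolan) all points of that group are signals not well above background.

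Probes differed by the family of their ID. CU probes bright enough to test were mostly higher after diofenolan: of 391 tested, 298 (76.2%) were higher and 5 (1.28%) lower, with a median log2 fold change of 0.96 and quartiles of 0.60 and 1.44. In the same arrays the median of the 18299 tested DM probes was -0.04 (9.95% higher, 11.1% lower) and that of the 7116 DMAG probes -0.01 (12.3% higher, 10.6% lower). Of the MF probes only 10 of 677 were bright enough to test, and 7 of them were higher. The median CU level per array rose from -2.43 ± 0.10 to -1.49 ± 0.04 (SD, n = 4 each; exact permutation test, 2-sided, p = 0.0286, the smallest that 4 against 4 allows). CU probes were dim, 59 of the 391 being well above background on none of the DMF arrays; over the 233 that were so on all 8 arrays the median was 0.83, and with no filter, over all 1388 CU probes, it was 0.35 with 293 higher and 5 lower. The size of the CU difference depended on the background correction, with medians of 0.54 (normexp from the negative controls), 0.38 (normexp then quantile normalization) and 0.19 (normexp then the 75th percentile, with 22 probes higher). The 0.38 and 0.19 come from the planned normexp, whose fit left a raised floor on DMF array 3. All of these corrections added an offset of 50, which draws dim signals together. ETG10_236652, one of the control probes of the array, moved with them, from -2.89 ± 0.16 to -1.76 ± 0.09 (SD, n = 4 each; exact permutation test, p = 0.0286). Without CU and MF probes, a choice made after the data were seen, 5381 probes were changed, 2662 higher and 2719 lower.

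**Figure D3:**
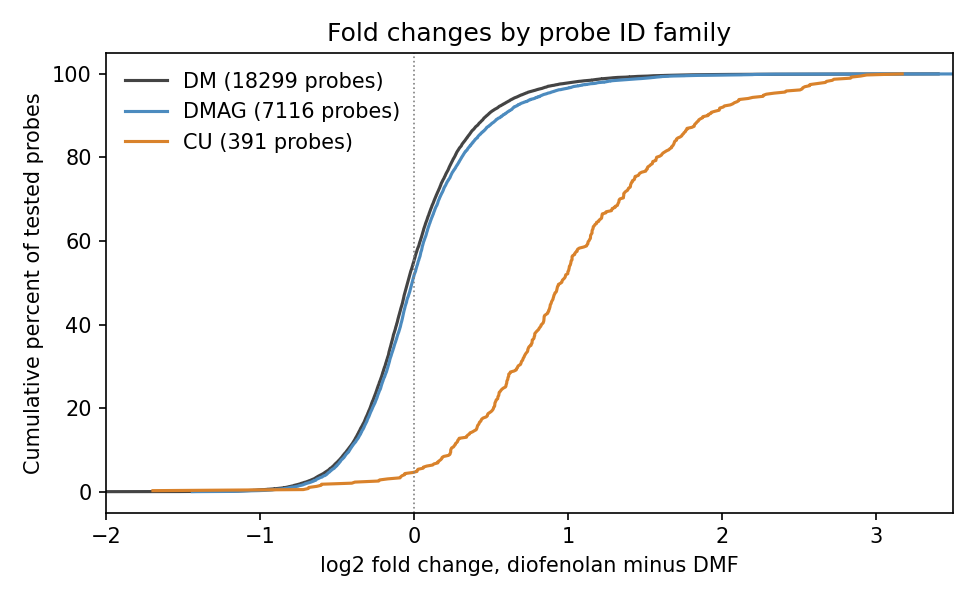
Cumulative percent of tested probes (vertical axis) against log2 fold change, diofenolan minus DMF (horizontal axis), for probes whose IDs start with DM, DMAG or CU. The CU curve lies to the right, with a median of 0.96 against -0.04 and -0.01.

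Probes that read separate stretches under one ID stem, taken as sharing no run of 20 bases, moved alike in most cases. Among 6113 such pairs of DM probes, log2 fold changes correlated with r = 0.562 (rho = 0.601, across probes, which are not independent replicates). Where at least 1 of the pair was called, 84.4% of 1949 pairs went the same way, against 51.8% on average with mates shuffled between stems. Of 493 pairs with both called, 477 agreed in sign. Probes of identical sequence correlated with r = 0.896 over 2631 sequences.

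These calls come from limma's moderated test on 8 arrays with an adjusted p under 0.05, which 22.4% of the tested probes met. The groups of 5429 changed probes did not overlap, which a call nearly requires. Of all tested probes 28.0% were separated in this way, against 2.86% for a probe whose 8 arrays are interchangeable. All probes share the same arrays, so a slide difference would raise that share too, and it is no separate support for the calls. The count of changed probes was 3788 without diofenolan replicate 2, 3390 with no filter on dim probes and 3709 with no normalization between arrays. It was 98 with normexp background correction and the 75th percentile, where the fitted background left a raised floor on DMF array 3. The same correction with quantile normalization gave 7396.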

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

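Of the tests in this part, those of the DCP ratios, of the probe mates, of transcripts raised by diofenolan and of the spike-in signals were chosen after the result had been seen, and the removal of the GC and length trend was added after other results had been. Of 32 pairs of a measure and a group examined for an array far from the others, 1 stood out, where chance gives about 1 in 20.

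The first pattern is the rise of the CU probes. Their median excess over DM and DMAG probes matched on signal, GC content and length was 0.85 on the log2 scale (95% bootstrap interval 0.79 to 0.90, 385 probes). This argues against those properties as the cause. The interval resampled probes, all read on the same 8 arrays, so it holds no spread between arrays or slides. Control data that no comparison used also differed between the groups, though not all one way. Mean log2 spike-in signals were 2.475 to 2.509 on the diofenolan arrays, below the 2.641 to 2.734 of DMF arrays 1 to 3. DMF array 4 stood lower still, at 0.66. The control ETG10_236652 was higher by 1.14 on the diofenolan arrays, and the DCP controls, read as the log2 ratio of 4 members to the member numbered 0 of their series on the same array, stood higher by 0.32 (-2.19 ± 0.05 against -1.88 ± 0.04, SD, n = 4 each; exact permutation p = 0.0286). Signals fall along a DCP series, so if its later members are poorer matches to one spike-in RNA, a meaning the files do not state, looser hybridisation on the diofenolan slide is a candidate explanation of a rise in probes that match no abundant transcript well, although the negative controls differed by only 0.10 (exact permutation p = 0.371) and the dimmest 20% of DM and DMAG probes had a median log2 fold change of 0.03. Transcripts raised by diofenolan stay open for the 298 risen CU probes and cannot be told apart from the slide, as no slide held both groups.

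The second pattern is the count of 5795 changed probes. Among the 35 splits of the arrays, 1 (the real one) gave as many, and the highest of the others gave 0. This cannot exclude chance as its source, since 1 in 35 is the least such a test can give. Every other split also mixes the slides, so a slide or group difference widens its spread and lowers its count. Hybridisation peculiar to single probes is argued against as the whole cause for DM probes, the only ones with mates. Their mates on separate stretches went the same way in 84.4% of pairs with a call (exact 95% interval 82.8% to 86.0%). That interval treats pairs as independent, though all were read on the same 8 arrays. The mate went the same way for 80.4% of probes called higher and 91.1% of those called lower. A smooth trend with GC content and length is argued against likewise, with 5484 changed probes after it was removed. Of these, 4850 were among the 5795, so some calls did depend on that trend. Also open is any difference in RNA, labelling or handling that went with the slides, which cannot be told apart from diofenolan.

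The third pattern is a low spike-in signal on DMF array 4. The mean log2 signal of 6 spike-in probes, relative to the array's 75th percentile, was 0.66 there and 2.64 to 2.73 on the other DMF arrays. A dimmer array as a whole is argued against, as its 75th percentile lay only 0.28 below the others on the log2 scale where the spike-ins lay 2.31 below. Less spike-in RNA for the sample RNA is a candidate explanation, as all 6 spike-in probes fell. The fall ran from 1.69 to 2.68 (SD 0.34), so it was not equal for all of them. No biological explanation was tested, and 4417 probes were changed without that array.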

How the results depend on the processing

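The count of 5795 changed probes stayed within 1.5 times under 21 of 28 alternatives, of which those that removed CU and MF probes (5381), averaged sequences (5303) or ID stems (4476), removed a GC and length trend (5484) or an intensity trend (5538), or took normexp from the negative controls (7840) were chosen after the data were seen. It was 3709 with no normalization between arrays and 3390 with no filter, where 43800 probes were tested, and the cause was not tested further. Stricter thresholds by construction gave 2050 at an adjusted p under 0.01 and 821 with an absolute log2 fold change of at least 1. Leaving out each array gave 3788 to 5949, the lowest without diofenolan replicate 2. With the replicate number (the slide position) as a block it was 3786. Same-numbered arrays deviated with correlations of -0.05, -0.07, -0.05 and 0.05, none closest to its own number, but pairing stays unsettled. The planned normexp correction gave 7396 with quantile normalization and, with the 75th percentile, 98, all higher; its negative controls came out at 888 on DMF array 3 against 72.8 to 94.0 elsewhere, and normexp fitted from the negative controls removed that gap.

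For the named probes, 57 of 61 values kept their direction and call, the others being lost under the planned normexp with the 75th percentile; DM09502_2 was too dim to test without DMF replicate 1, 3 or 4. With normexp from the negative controls, whose offset of 50 draws dim signals together, the log2 fold changes were 2.45 (DM12433_2, 3.41 in the report) and -0.92 (DM05284_2, -1.78), and the bounds at least 3.36-fold (DMAG0001S00005486) and 1.06-fold (DM09502_2). The CU median ran from 0.19 to 0.97 over 24 settings, some (block, moderation, value table) unable to move it. It was 0.19, 0.38 and 0.54 under normexp with the 75th percentile, with quantile normalization and from negative controls. Of 72 values of the motif groups, all from alternatives not planned for these groups, 65 kept their call. The cuticle group stayed between 0.23 and 0.60 with its preset-correlation call kept in all 18. That call is lost with an estimated correlation (camera adjusted p = 0.159). Ubiquitin probes passed under the block and without DMF replicate 4 or diofenolan replicate 1 or 2. The ubiquitin (0.21), trypsin-type (0.18) and thioredoxin fold (0.30) groups passed under normexp with the 75th percentile. A slide block, gene lists and genes as the unit were not run, for want of a slide with both groups and of gene names. Signal over background limits both directions, as DMAG0001S00005486 was well above background on 0 DMF arrays and DM09502_2 on 0 diofenolan arrays.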

Other observations

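All values in this part were chosen for report after the data had been seen. Signals were set out by the strand that carries a motif, with no test of the difference and different sequences on each strand. Of 26 probes that encode the trypsin-type motif as printed, 19 were well above background on at least 4 arrays, against 6 of 14 that encode it on the opposite strand. For the cuticle protein motif the counts were 6 of 9 and 3 of 8. For the collagen-like repeat the counts were 22 of 35 and 6 of 22, though 14 reversed sequences also matched, so this group was not tested. C-type lectin probes went the other way, with 4 of 5 and 6 of 7, and EF-hand probes had 2 of 2 and 4 of 5.

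Both strands of 111 sequences were on the array. Of these pairs, 44 had both strands bright enough to test, 57 had one and 10 had neither. Over the 44 pairs the log2 fold changes of the strands correlated with r = 0.228 across probes, which are not independent replicates.

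Within the CU family, 7 of the 1388 probes share a run of 20 bases with a DM or DMAG probe, and all 7 were bright enough to test. Their median log2 fold change was -0.38, against 0.96 for the 384 tested CU probes that share none. The number is small and the difference was not tested. Of the DCP controls taken singly, the ratios of DCP_22_4 and DCP_22_6 were higher on the diofenolan arrays by 0.29 and 0.49 (exact permutation p = 0.0286 each, n = 4 per group). Those of DCP_20_3 and DCP_20_5 differed by 0.19 and 0.30 (exact permutation p = 0.0571 and 0.114), and these tests were not adjusted for their number.

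Among DM and DMAG probes the balance of calls moved with GC content and signal. In the 20% of probes with the lowest GC content 14.8% were higher and 5.39% lower, and in the 20% with the highest 12.4% and 14.2%. In the dimmest 20% 11.4% were higher and 5.59% lower, and in the brightest 6.41% and 14.3%.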
